A study of Mus musculus with 6 samples.

How the data were processed

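Single-cell RNA from YFP positive, IgD negative B cells of the spleen was measured in 6 mice, 3 with wild-type Ezh2 and 3 with a conditional Y641F allele, with 10X Genomics 3' version 2 chemistry per the labels. The deposited files hold whole-number UMI counts per gene and cell, without normalization, and per the submitters' processing notes these counts were made by the authors with Cell Ranger 3.0.2 on genome build mm10. Their gene annotation is not stated, and the deposited matrices hold cells that had already been selected. They list 27998 genes, of which 0 are immunoglobulin genes, so isotypes and immunoglobulin constant genes were not analysed here. The lowest UMI total of a cell was 1894, 2138 and 1926 in wild type mice 1 to 3 and 2107, 2491 and 2867 in Y641F mice 1 to 3. Median UMIs per kept cell were 3771, 3794 and 3215 in wild type and 4231, 3647 and 4154.5 in Y641F mice. The labels give no sequencing batch or date, and name litter 1 for each mouse.

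Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept. Doublets were scored per library with Scrublet (scanpy 1.11.5, expected rate 0.04) and 140 cells (0.818%) were left out, between 0.04% of Y641F 1 and 2.503% of Y641F 2. Kept cells numbered 2081, 1943 and 1841 in wild type and 4743, 3221 and 1624 in Y641F mice. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes chosen per library, 30 principal components and 15 nearest neighbours (scikit-learn 1.9.0) gave a graph that was clustered with the Leiden method (leidenalg 0.10.2, resolution 1.0, seed 1) in Python 3.11.15. Clusters were assigned to classes by marker lists: light zone-like (cluster 0), cycling GC-like (S phase clusters 5, 7 and 8, G2/M clusters 3 and 9), GC-like without a zone (6 and 16), memory-like (1 and 12), plasma-like (2, 4, 10 and 14), and erythroid, myeloid and T cells, which stayed out of the B cell comparisons. Classes are named "-like" because they rest on RNA alone. Among GC-like clusters, cluster 0 scored 0.975 on light zone, 1.155 on naive and follicular, 0.997 on memory and -0.206 on GC pan markers. Its name therefore does not exclude memory-like or naive-like cells within it.

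Raw UMI counts were summed per mouse and class, so that the mouse is the unit of replication (n = 3 per genotype). Genes were filtered with filterByExpr, scaled with TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjusted p and a threshold of 0.05. The interaction was tested over 12 sums of light zone-like and cycling cells with mouse as a block. Of the genes tested, the smallest class sums held 344233 UMIs (light zone-like) and 510713 UMIs (memory-like). The values of the genotypes did not overlap for 17.8% of genes in light zone-like, 26% in cycling, 28.7% in plasma-like, 17.5% in memory-like cells and 20.9% over all B cells, where chance gives 10%. Log2 fold changes are Y641F over wild type. Gene lists fixed in advance were tested with camera of limma 3.58.1 (preset correlation 0.01) in light zone-like cells, cycling cells and all B cells: 39 of 44 lists had at least 3 measured genes and gave 115 tests, of which 24 passed after adjustment over them together. With an estimated correlation 0 passed (8 at an unadjusted p under 0.05, lowest adjusted p = 0.617), and with fry 0 passed (15 at an unadjusted p under 0.05, lowest adjusted p = 0.0593). Shares of cells were compared with two-sided exact permutation tests, and cell numbers over 9 classes with edgeR.

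The comparisons, tests, gene lists, class markers and most alternatives were chosen before the data were examined. Genes are named by a rule fixed at that time. It takes Ezh2 first, then among genes with an adjusted p under 0.05, a mean of at least 20 CPM and genotypes that do not overlap, the 12 with the largest rise and the 12 with the largest fall in light zone-like and in cycling cells and the 6 each way elsewhere, leaving out immunoglobulin segments and predicted gene models. Outside that rule, members of the gene and marker lists are named where a list is described, leading genes where a cluster is described, and Cbfa2t3 and C130026I21Rik because they passed in 4 classes. Positions are from GENCODE M21 (GRCm38), in which 89 of 90 named genes were found.

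Whether equal mouse numbers mark pairs was checked from the data, since the labels do not say so. Deviations from the group means correlated at 0.633, 0.268 and 0.342 between mice of equal number in the sums of all B cells, over 0.1 in each pair, so the value with the number as a block stands beside that result. Mice of unequal number also correlated, wild type 3 with Y641F 2 at 0.277 and wild type 2 with Y641F 3 at 0.187, so the mice numbered 2 and 3 are not told apart by this check. The numbers are those of the sample titles. The deposited files number the wild type mice 2 to 4, and by those numbers wild type 1 and 2 would share a number with Y641F 2 and 3, with correlations of -0.447 and 0.187. The blocked result therefore depends on the numbering, and it was not run with the file numbers. In the single classes at least 1 pair was under 0.1. GC-like cells made up 71.6% of the B cells of wild type 1 and 82.2% of those of Y641F 1, but 40% to 52.2% in the other mice. Pairing was therefore not told apart from the mix of classes in the sums of all B cells.

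The tests were run on simulated data with the means and library sizes of the real sums and their fitted trend of spread. In each run 100 genes were changed by 1.5-fold and 100 by 2-fold. edgeR recovered 22% and 75% of them in all B cells, 36% and 73% in light zone-like, 65% and 92% in cycling, 21% and 79% in plasma-like and 34% and 71% in memory-like cells and 23% and 57% in the interaction. False calls made up 3.96%, 3.54%, 4.27%, 3.85%, 2.78% and 1.23% of calls in the same order. The interaction was simulated on 6527 genes that were tested in both classes, whereas the real interaction was tested on 9471. There the sums of a mouse were drawn independently, without the shared mouse effect that the block takes up. In all comparisons genes of like mean were given like spread, and each came from a single draw. These shares therefore do not give the error rate on the real sums. Camera found a list changed by 1.25-fold and called 0 of the other lists among 38. Genes were drawn independently there, so that run cannot show how often correlated genes lead camera to call lists. In the real data, other splits of the mice into 3 and 3 gave up to 44 list calls.

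Alternatives were DESeq2 1.42.0, other scalings and count filters, a block for mouse number, leaving out each mouse, other limits on mitochondrial share and genes per cell, doublets kept, other resolutions, centring per library, clustering without called genes, and thinning each cell to 2900 UMIs. Chosen after the data were seen were a term for the mice numbered 1 against 2 and 3, plasma-like cells without cluster 14 or from cluster 4 alone, memory-like cells without cluster 12, other definitions of the light zone-like share, and gene list tests with thinned cells and with clustering without called genes. The erythroid, myeloid and T cells were too few or outside the question and were not compared for gene expression.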

Results

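Gene expression was measured in single B cells sorted as YFP positive and IgD negative from the spleens of 6 female C57BL/6J mice, aged 10 weeks and immunised 8 days earlier with sheep red blood cells. This antigen induces germinal centres (GCs), the follicular structures in which B cells mutate their antibody genes and are selected. YFP is switched on by a Cre recombinase expressed from the immunoglobulin gamma 1 locus, so the sort takes B cells in which that locus was active and their descendants. GC B cells are among them, but passage through a GC was not traced. In 3 mice Ezh2 was wild type, and 3 mice carried a conditional Ezh2 Y641F allele beside a wild-type allele. EZH2 is the catalytic subunit of PRC2, the complex that places a repressive methyl mark on histones, and Y641F is a recurrent lymphoma mutation in its catalytic domain. Per the labels, 10000 cells were loaded per spleen. The files held 2413, 2294 and 2075 cells from wild type mice 1 to 3 and 4953, 3596 and 1785 cells from Y641F mice 1 to 3. Their unique molecular identifier (UMI) totals were 11709598, 11163522 and 9413146 in the wild type and 26653876, 16801339 and 10700589 in the Y641F libraries. Filters kept 15453 of 17116 cells. Cells with over 10% mitochondrial UMIs made up 13.5%, 14.7% and 10.7% of the wild type and 4.20%, 8.06% and 8.24% of the Y641F libraries.

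Ezh2 itself (ENSMUSG00000029687, chromosome 6, 47530139 to 47595341, GRCm38) was read in every library. In cycling GC-like cells it stood at 223 ± 9.32 CPM (counts scaled to library size; SD, n = 3) in wild type and 188 ± 11.9 CPM in Y641F mice (log2 -0.25, adjusted p = 0.0721, edgeR). In light zone-like cells it stood at 62.2 ± 6.48 and 50.7 ± 10.9 CPM (log2 -0.17, adjusted p = 0.770). In memory-like cells it stood at 61.7 ± 10.5 and 52.2 ± 7.41 CPM (log2 -0.32, adjusted p = 0.394), and over all B cells it stood at 136 ± 3.57 and 114 ± 15.7 CPM (log2 -0.25, adjusted p = 0.421). In plasma-like cells Ezh2 fell by 0.59 on the log2 scale, from 58.6 ± 1.38 to 39.9 ± 8.86 CPM (adjusted p = 0.0278). That call was lost without any of wild type 1, 2 and 3 or Y641F 1 and 2, with log2 values over all left-out libraries of -0.76 to -0.40, and within cluster 4 alone the value was 0.15. Counts from transcript 3' ends do not tell the alleles apart, so these values do not check the genotype.

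The series is about how Ezh2 mutation changes the GC reaction, and the first comparison asked whether the makeup of the sorted cells differed. Light zone-like cells, the counterpart of the centrocytes that are selected by T cells and follicular dendritic cells, made up 23.5% ± 8.22 of GC-like cells in wild type and 23.6% ± 8.08 in Y641F mice (SD, n = 3 each, exact two-sided permutation p = 1). Memory-like cells made up 17.4% ± 3.58 of B cells in wild type and 9.34% ± 0.548 in Y641F mice, a difference of -8.04 percentage points. All 3 Y641F mice lay below all 3 wild type mice, and the exact permutation p of 0.1 is the smallest that 3 against 3 can give. By mouse, memory-like shares were 14.1% (95% Wilson interval 12.7 to 15.7), 21.2% (19.4 to 23.1) and 16.8% (15.1 to 18.6) in wild type and 9.41% (8.61 to 10.3), 9.84% (8.85 to 10.9) and 8.76% (7.41 to 10.3) in Y641F. These intervals cover counting error only.

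Plasma-like cells made up 26.8% ± 11.2 and 32.5% ± 21.6 of B cells (exact permutation p = 0.7), with single Y641F mice at 8.41%, 50.1% and 39.1%. The difference of 5.68 points turned to -0.595 without wild type 1 and to -3.11 without Y641F 2, and reached 17.7 without Y641F 1. GC-like cells as a whole made up 55.8% ± 13.7 and 58.1% ± 21.7 of B cells (exact permutation p = 0.8). Cycling cells made up 62.9% ± 8.52 and 65.9% ± 11.3 of GC-like cells (exact permutation p = 0.8). GC-like cells that matched neither zone, in clusters 6 and 16, made up 13.6% ± 2.05 and 10.5% ± 3.59 (exact permutation p = 0.2). An edgeR test over the 9 classes called 0, with 1 class, memory-like cells, at an unadjusted p under 0.05 (log2 -0.90, SE 0.338, adjusted p = 0.296). The light zone-like difference of 0.146 points lay far inside the spread between mice and turned negative without wild type 2 (-0.968), wild type 3 (-3.29), Y641F 1 (-2.03) or Y641F 2 (-2.34). It reached 4.70 without wild type 1, 4.81 without Y641F 3, 6.38 with thinned cells (exact permutation p = 0.2) and 14.4 with centring per library before clustering (exact permutation p = 0.6). The sort and the capture of cells set what these shares can show.

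**Figure D1:**
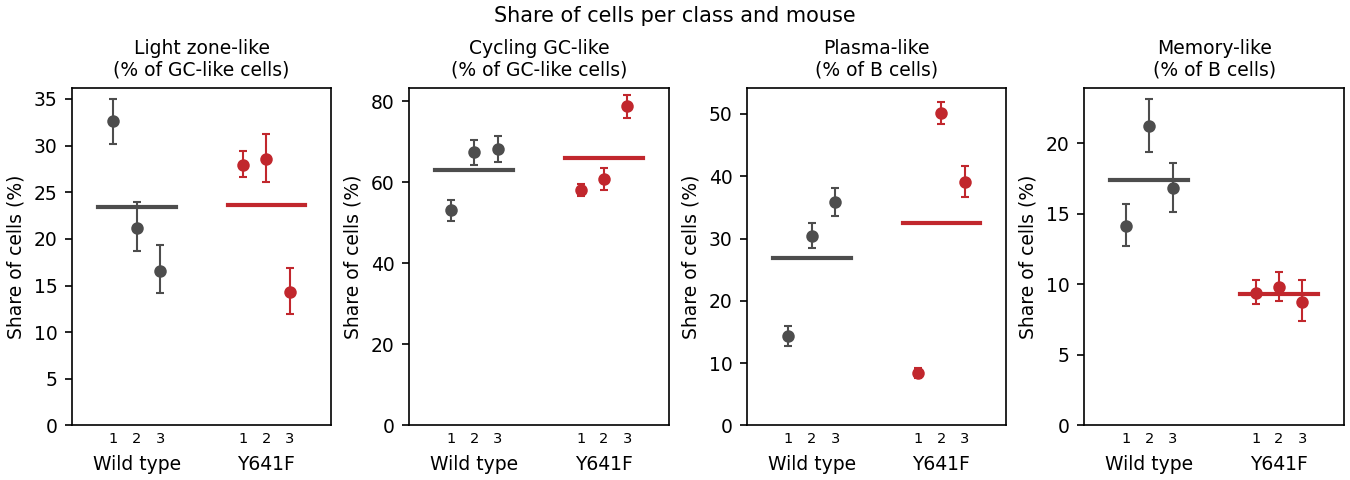
Share of cells per class and mouse, in percent of GC-like cells (light zone-like, cycling) or of B cells (plasma-like, memory-like), with 95% Wilson intervals for counting error as bars and group means of 3 mice as horizontal lines. Memory-like shares of the Y641F mice lie between 8.76% and 9.84%, below the lowest wild type share of 14.1%.

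The second comparison asked what differed between genotypes within light zone-like cells. Lmo2, a transcriptional cofactor expressed in GC B cells, fell from 195 ± 12.5 to 52.2 ± 11.1 CPM (SD, n = 3; log2 -1.84, SE 0.156, adjusted p = 1.83e-12, edgeR). Gadd45g, a growth arrest and stress response gene, fell from 47.1 ± 10.1 to 6.54 ± 3.26 CPM (log2 -3.14, SE 0.298, adjusted p = 5.05e-11). Notch2, a receptor that directs marginal zone B cell fate, fell from 48.4 ± 7.55 to 12.7 ± 0.373 CPM (log2 -1.86, adjusted p = 6.68e-07). Cd200, an inhibitory surface ligand, fell from 55.2 ± 12.4 to 17.1 ± 4.45 CPM (log2 -1.56, adjusted p = 1.44e-05). Apoe, the lipid carrier apolipoprotein E, rose from 950 ± 213 to 1971 ± 170 CPM (log2 1.04, SE 0.125, adjusted p = 4.40e-08). Suclg2, a subunit of the tricarboxylic acid cycle enzyme succinyl-CoA ligase, rose from 37.8 ± 8.04 to 89.1 ± 16.6 CPM (log2 1.11, adjusted p = 9.74e-05). Gh, the growth hormone gene, rose from 25.7 ± 2.41 to 62.4 ± 14.2 CPM (log2 1.36, adjusted p = 2.32e-05).

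In all, 189 of 6533 genes passed, 59 higher and 130 lower in Y641F mice. Other large falls were in Itgb7 (log2 -1.81), the beta 7 integrin chain, Rnf130 (-1.66), Birc5 (-1.58), which encodes survivin, B3gnt5 (-1.56), Serpinb1a (-1.50), Nrip1 (-1.49), Gng12 (-1.48) and Sgk3 (-1.42). Other large rises were in Blm (1.23), the Bloom syndrome helicase, Litaf (1.09), Ggnbp1 (1.08), Lxn (1.02), Hbb-bt (0.97), Fam53b (0.96), Tuba4a (0.96) and Pik3r4 (0.90). AC168977.1 rose from 4.24 ± 2.15 to 53.2 ± 3.22 CPM (log2 3.53, adjusted p = 5.05e-11), and its identifier has no position in the annotation used. It passed in cycling (log2 3.36), plasma-like (3.96) and memory-like cells (3.73) as well, and a difference of strain or construct between the mice was not tested as its origin. Lmo2 lies on chromosome 2 (103957986 to 103981878), Gadd45g on chromosome 13 (51846678 to 51848468), Notch2 on chromosome 3 (98013527 to 98150361), Cd200 on chromosome 16 (45382135 to 45409053), Apoe on chromosome 7 (19696109 to 19699188) and Suclg2 on chromosome 6 (95473009 to 95718800), all protein coding in GRCm38. Without wild type 1 the calls of Blm (log2 0.97), Itgb7 (-1.47) and B3gnt5 (-1.06) were lost. Those of Ggnbp1, Fam53b, Tuba4a and Pik3r4 were each lost without at least 2 of the libraries, with log2 values of 0.73 to 1.88 over all left-out libraries. The count was 88 without Y641F 2, 121 without wild type 1, 401 without Y641F 3 and 58 with DESeq2. With centring per library before clustering, 13 of the 24 named genes did not pass, Apoe (log2 0.14, adjusted p = 0.917) among them. With thinned cells 9 of the 18 that had a value did not, Notch2 (-1.69, adjusted p = 0.0778) among them. With a 5% mitochondrial limit 9 of 19 did not, Gh (0.83, adjusted p = 0.0661) among them.

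**Figure D2:**
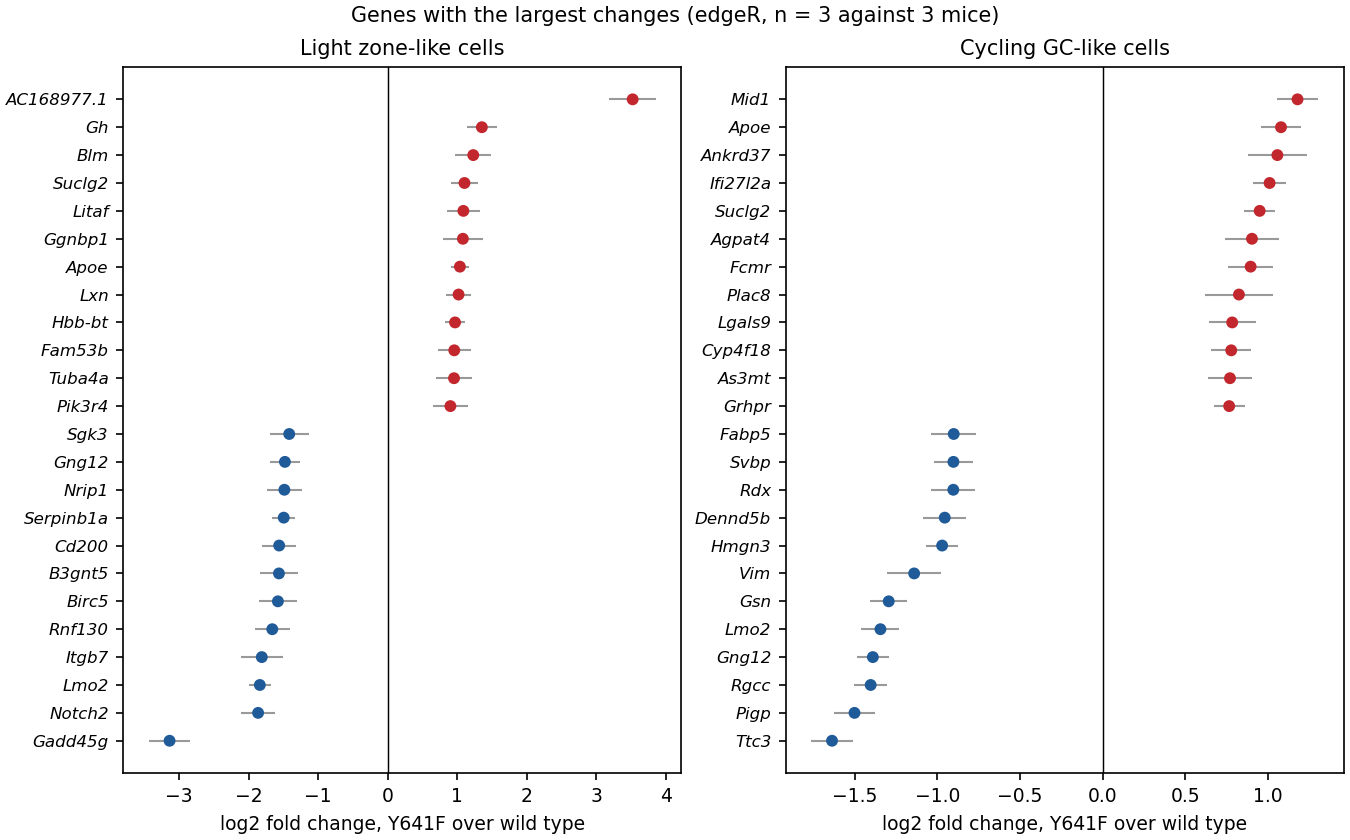
Log2 fold change of Y641F over wild type for the 12 genes with the largest rise (red) and the 12 with the largest fall (blue) in light zone-like and in cycling GC-like cells, from edgeR on counts summed per mouse (3 against 3), with standard errors as bars. Lmo2 and Gng12 fell and Apoe and Suclg2 rose in both panels.

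Gene lists fixed before the data were examined were tested next in light zone-like cells. Of 38 lists, 10 passed camera and 0 passed with an estimated correlation. Over light zone-like, cycling and all B cells together, 24 list tests passed camera. At least 24 passed in 8 of the 10 splits of the mice into 3 and 3, the real one included, and up to 44 in another split. A camera pass here or below therefore does not by itself mark an effect of genotype. Of 23 light zone genes measured, 6 fell and 17 did not pass (9 fell when adjusted over the list alone), with a median log2 of -0.34. The 6 were Lmo2, Cd69 (log2 -1.08), an early activation marker, Fcer2a (-0.84), the low-affinity IgE receptor, Cd83 (-0.73) and Cd86 (-0.56), surface proteins of antigen-presenting cells, and Basp1 (-0.70). The list passed camera at adjusted p = 3.03e-08, with adjusted p = 0.617 with an estimated correlation. Of 16 cell cycle inhibitors and differentiation genes known as PRC2 targets in GC B cells, 5 fell and 11 did not pass (7 fell when adjusted over the list alone), with a median log2 of -0.44 (camera adjusted p = 7.37e-05, adjusted p = 0.617 with an estimated correlation). They were Cdkn2c (log2 -1.30), which encodes the cell cycle inhibitor p18, Cd69, Cd38 (-1.05), Klf2 (-1.05), a quiescence and trafficking factor, and Zbtb20 (-0.50). Of 16 memory and egress genes, 5 fell and 11 did not pass (7 fell when adjusted over the list alone; median log2 -0.58; camera adjusted p = 3.67e-07, adjusted p = 0.682 with an estimated correlation), among them Itgb7, Cd55 (log2 -1.19), a complement regulator, Cd38 and Klf2. Only Vim and S100a10 of the memory marker list are not memory and egress genes, so it is not a separate result. The PRC2-target list also shares Cd38, Klf2, Hhex, Bcl2, S1pr1 and Gpr183 with both. The memory marker list had the same median of -0.58 (5 of 14 fell, 8 when adjusted over the list alone, camera adjusted p = 7.02e-07, adjusted p = 0.682 with an estimated correlation). The naive and follicular marker list had a median of -0.46 with 5 of 10 lower, among them Btg1 (log2 -0.63), and Fcmr (0.76), the IgM Fc receptor, higher, counts that were equal when adjusted over the list alone (camera adjusted p = 3.15e-03, adjusted p = 0.867 with an estimated correlation). Without wild type 1 that list no longer passed (median -0.35, adjusted p = 0.229), and its median was -0.31 without Y641F 2 and -0.80 without Y641F 1. Without wild type 1 the PRC2-target median was -0.29, and without Y641F 1 the medians of memory and egress genes and memory markers were -0.88 and -0.94. The cluster that forms this class also scored high on memory (0.997) and on naive and follicular markers (1.155). Falls of these lists were therefore not told apart from a change in the mix of cells within the class.

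The G2/M list also passed as lower in light zone-like cells. Of 21 G2/M phase genes, 3 fell and 18 did not pass (9 fell when adjusted over the list alone), with a median log2 of -0.54: Birc5, Cdca3 (log2 -1.39) and Cdk1 (-1.31), the mitotic kinase (camera adjusted p = 8.67e-06, adjusted p = 0.617 with an estimated correlation). S phase genes had a median of 0.00 over 25 members (camera adjusted p = 0.790), with Blm higher. The glycolysis and hypoxia list passed as higher (median log2 0.25): 3 of 15 rose and 12 did not pass (7 rose and 1 fell when adjusted over the list alone), namely Pfkp (log2 0.77) and Gpi1 (0.47), enzymes of upper glycolysis, and Gapdh (0.50), with camera adjusted p = 9.79e-04 and adjusted p = 0.617 with an estimated correlation. Ribosomal protein genes had a median log2 of 0.25, with 3 of 85 higher and 2 lower (38 and 4 when adjusted over the list alone; camera adjusted p = 6.12e-11, adjusted p = 0.889 with an estimated correlation), while 25 annotated pseudogenes, 8 of them named after ribosomal protein genes, had a median of -0.45, with 4 lower. Genes for contact with follicular dendritic cells (median log2 0.02, 18 members, camera adjusted p = 0.825) and with T follicular helper cells (median -0.06, 15 members, 2 lower, Cd83 and Cd86, both also when adjusted over the list alone with 3 higher, camera adjusted p = 0.346) did not pass as lists. Unfolded protein response genes (median log2 0.18, Ddit4 higher, camera adjusted p = 0.0174, adjusted p = 0.867 with an estimated correlation) and GC pan markers (median -0.06, Lmo2 lower, camera adjusted p = 0.0384, adjusted p = 0.867 with an estimated correlation) passed, but the first did not without wild type 1 (adjusted p = 0.0583), Y641F 2 (0.0506) or Y641F 3 (0.120). The other did not without wild type 2 (0.0541), wild type 3 (0.150, with the median turned to 0.01), Y641F 2 (0.0763) or Y641F 3 (0.354). Dark zone genes outside the cell cycle did not pass (median -0.07, 15 members, camera adjusted p = 0.666).

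Markers of other cells were read in the same sums. The erythroid gene Hbb-bt rose to 467 ± 87.4 CPM from 239 ± 49.0. Hbb-bs passed as lower (fitted log2 -1.63, adjusted p = 0.0243), with 16.2, 28.5 and 17.3 CPM in wild type and 3.07, 7.78 and 25.7 CPM in Y641F mice, so that Y641F 3 lies among the wild type values and the means of 20.7 and 12.2 CPM differ less than the fitted value. The neutrophil gene S100a8 passed as lower (log2 -2.96, adjusted p = 6.04e-03), but its wild type values were 0.736, 17.8 and 168 CPM, so that wild type 3 sets its mean of 62.1 CPM against 7.71 CPM. Tyrobp, an adaptor of myeloid and natural killer cells, rose from 11 to 25 CPM (log2 1.32, adjusted p = 9.08e-03), and Lck, the only T cell marker measured here, from 110 to 170 CPM (log2 0.60, adjusted p = 0.0160). Lck is also among the leading genes of cluster 0, the light zone-like cluster itself, so its rise does not by itself mark T cells. Neither the erythroid (camera adjusted p = 0.397) nor the myeloid list (camera adjusted p = 0.793) passed. T cells made up 0.218% ± 0.103 of kept cells in wild type and 0.108% ± 0.055 in Y641F mice (exact permutation p = 0.3). Myeloid cells made up 2.12% ± 1.58 and 1.46% ± 1.33 (exact permutation p = 0.6), and erythroid cells 1.47% ± 1.24 and 3.07% ± 3.5 (exact permutation p = 0.7). Whether RNA of these cells entered the sums was not tested.

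**Figure D3:**
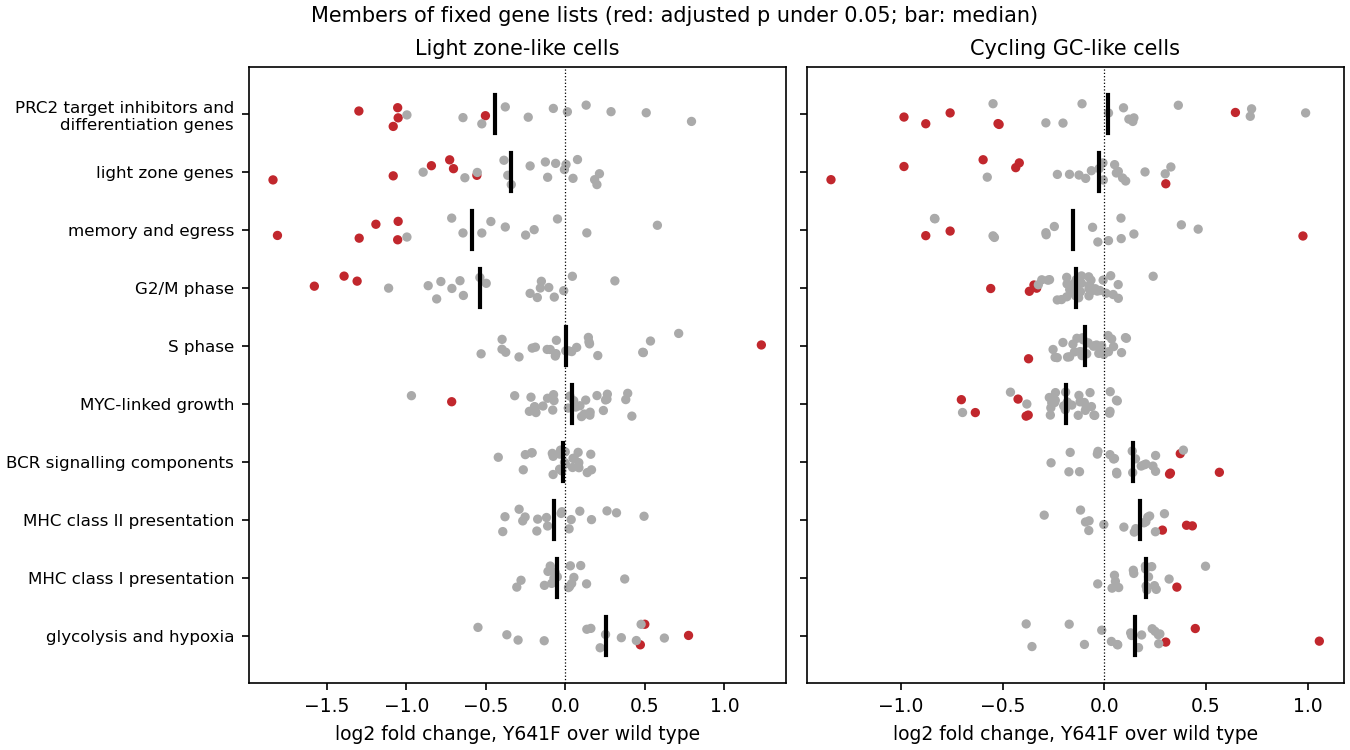
Log2 fold change of Y641F over wild type for each measured member of 10 gene lists in light zone-like and in cycling GC-like cells, with members that passed at an adjusted p under 0.05 (edgeR) in red and the list median as a black bar. In light zone-like cells the medians of the light zone and G2/M lists are -0.34 and -0.54, and in cycling cells the medians of the antigen presentation lists are 0.17 (class II) and 0.20 (class I), and 0 lists passed with an estimated correlation.

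The third comparison took cycling GC-like cells, the counterpart of the dividing centroblasts. Rgcc, a regulator of cell cycle kinases, fell from 115 ± 4.15 to 44.7 ± 5.6 CPM (SD, n = 3; log2 -1.40, SE 0.10, adjusted p = 7.21e-08, edgeR). Gng12, a G protein gamma subunit, fell from 116 ± 10.5 to 44.6 ± 1.94 CPM (log2 -1.39, SE 0.0962, adjusted p = 7.21e-08). Ttc3 (log2 -1.64) and its neighbour Pigp (-1.50) and Lmo2 (-1.34) fell as well. Lower too were Gsn (-1.29), which encodes the actin-severing protein gelsolin, Vim (-1.14), the intermediate filament vimentin, and Rdx (-0.90), the membrane linker radixin. Mid1, a microtubule-associated ubiquitin ligase, rose from 16.1 ± 1.26 to 36.3 ± 2.86 CPM (log2 1.18, SE 0.126, adjusted p = 9.40e-06). Apoe rose from 281 ± 71.8 to 597 ± 13.8 CPM (log2 1.08, adjusted p = 1.61e-05) and the interferon-inducible Ifi27l2a from 262 ± 18.6 to 530 ± 77.0 CPM (log2 1.01, adjusted p = 3.50e-06).

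Of 9271 genes, 822 passed, 317 higher and 505 lower. Further large rises were in Ankrd37 (log2 1.06), a hypoxia-responsive gene, Suclg2 (0.95), Agpat4 (0.90), Fcmr (0.90), Plac8 (0.83), Lgals9 (0.78), which encodes galectin 9, Cyp4f18 (0.78), As3mt (0.77) and Grhpr (0.77). Further large falls were in Hmgn3 (-0.97), a nucleosome-binding protein, Dennd5b (-0.95), Svbp (-0.90) and Fabp5 (-0.90), a fatty acid binding protein. Ttc3 spans 94370618 to 94469343 and Pigp 94358763 to 94371842 on chromosome 16 (GRCm38), on opposite strands, so that their ends overlap. Rgcc lies on chromosome 14 (79288756 to 79301645), Mid1 on chromosome X (169685199 to 170005736) and Gng12 on chromosome 6 (66896397 to 67021350). The call of Plac8 was lost without wild type 1 (log2 0.54, adjusted p = 0.0990). The count was 358 without wild type 2, 540 without wild type 3, 498 without Y641F 1, 470 without Y641F 2 and 492 with DESeq2.

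The lists of growth and G2/M genes passed as lower in cycling cells. Of 35 MYC-linked growth and ribosome biogenesis genes, 5 fell and 30 did not pass, equal to the counts adjusted over the list alone, with a median log2 of -0.19 (camera adjusted p = 1.28e-04, adjusted p = 0.933 with an estimated correlation) that was -0.11 without wild type 3 (adjusted p = 0.0481). They were Phb (log2 -0.70), a mitochondrial scaffold protein, the RNA helicase Ddx21 (-0.42), Nme2 (-0.63), the chaperonin Hspd1 (-0.38) and Ranbp1 (-0.37), whereas Myc stood at log2 -0.46 (adjusted p = 0.0918). Of 42 G2/M phase genes, 4 fell and 38 did not pass, also when adjusted over the list alone (median log2 -0.14): Ttk (log2 -0.56), Ccnb1 (-0.37), Nusap1 (-0.35) and Aurka (-0.33), with camera adjusted p = 2.03e-03 and adjusted p = 0.889 with an estimated correlation.

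The lists of antigen receptor signalling and antigen presentation passed camera as higher, though most other splits of the mice gave as many camera passes or more. Of 25 BCR signalling components, 4 rose and 21 did not pass (6 rose when adjusted over the list alone), with a median log2 of 0.14: the receptor chain Cd79a (log2 0.32), the kinase Prkcb (0.37), Rasgrp3 (0.33) and Cd72 (0.57), an inhibitory coreceptor (camera adjusted p = 9.66e-03, adjusted p = 0.933 with an estimated correlation). Of 18 MHC class II presentation genes, 3 rose (8 when adjusted over the list alone), all encoding lysosomal proteins that process antigen: Lgmn (log2 0.43), Ifi30 (0.40) and Ctss (0.29), with a median of 0.17 (camera adjusted p = 0.0150, adjusted p = 0.867 with an estimated correlation). Of 18 MHC class I genes, Calr (log2 0.36), which encodes a chaperone of the peptide loading complex, rose (also when adjusted over the list alone), with a median of 0.20 (camera adjusted p = 3.93e-03, adjusted p = 0.924 with an estimated correlation). The glycolysis and hypoxia list passed as higher here too (3 of 20 rose, Ankrd37, Pfkp and Gapdh; 5 rose and 2 fell when adjusted over the list alone; median log2 0.15; camera adjusted p = 0.0438, adjusted p = 0.767 with an estimated correlation). The PRC2-target list did not pass: 5 fell, led by Cd69 (log2 -0.98), and Tgfbr2 (0.65) rose (5 and 4 when adjusted over the list alone), with a median of 0.02, a mean of -0.04 and camera adjusted p = 0.482. Without wild type 3 the BCR (median 0.08, adjusted p = 0.135) and MHC class II lists (median 0.14, adjusted p = 0.0771) no longer passed, and the MHC class I list did not without Y641F 2 (median 0.16, adjusted p = 0.0763). The BCR median was 0.22 without wild type 1. The glycolysis and hypoxia list did not pass without wild type 1 (adjusted p = 0.0506), wild type 2 (adjusted p = 0.140) or Y641F 2 (adjusted p = 0.0763). Ribosomal protein genes (median 0.13 although the 3 that passed fell, camera adjusted p = 0.0384, adjusted p = 0.938 with an estimated correlation) and GC pan markers (median -0.11, Lmo2 lower, camera adjusted p = 0.0287, adjusted p = 0.867 with an estimated correlation) passed too. The ribosomal list did not without wild type 2 (adjusted p = 0.0769), wild type 3 (0.0771), Y641F 1 (0.326) or Y641F 2 (0.156). The GC pan list did not without wild type 1 (0.0810), wild type 3 (0.0823) or Y641F 2 (0.119). Markers of other cells passed as higher in the same cycling sums: Hbb-bt (log2 0.62) of erythroid, Tyrobp (0.94) and Ctss of myeloid, Cst3 (0.43) and Flt3 (0.34) of dendritic, Thy1 (1.35) and Lck (0.55) of T and Pecam1 (0.67) of stromal cells, and Ctss is also a member of the MHC class II list. Lck is also a leading gene of the light zone-like cluster, as stated above. Mean shares of T and myeloid cells among kept cells were lower in Y641F mice, and that of erythroid cells was higher. The erythroid (camera adjusted p = 0.248), myeloid (0.346) and dendritic lists (0.170) did not pass. The 25 pseudogenes had a median log2 of -0.46 in these cells, with 18 lower.

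The fourth comparison asked whether the genotype difference itself differed between light zone-like and cycling cells. Birc5 and Cdca3, both genes of mitosis, were lower in Y641F light zone-like cells (log2 -1.58 and -1.39) but stood at -0.21 and -0.02 in cycling cells, differences between the effects of -1.35 each (SE 0.261 and 0.299, adjusted p = 2.56e-04 and 3.91e-03, edgeR). Dock10, a guanine nucleotide exchange factor, stood at -0.75 and 0.30 (difference -1.01, SE 0.161, adjusted p = 9.68e-07). Ttc3 stood at -0.31 and -1.64 (difference 1.39, adjusted p = 2.43e-04), and Blm at 1.23 and 0.09 (difference 1.18, adjusted p = 6.26e-03). In all 43 of 9471 genes passed, 14 with a more positive and 29 with a more negative difference in light zone-like cells. The count was 5 with DESeq2, 8 without Y641F 2, 15 without wild type 3, 26 without wild type 1 and 28 without wild type 2. Among settings that leave out no library, Birc5 did not pass with a 5% mitochondrial limit (-0.81), centring (-0.64) or thinned cells (-1.20), nor Dock10 with a 5% mitochondrial limit (-0.75) or thinned cells (-0.86), and Cdca3 went to -0.31 with centring. Of the same settings, Cdca3 did not pass in 6, DESeq2 (-1.44) and doublets kept (-1.15) among them. Ttc3 did not pass in 4, namely DESeq2 (1.26), a 5% mitochondrial limit (1.16), centring (1.31) and thinned cells (1.36). Blm did not pass in 7, those 4 and a 20% mitochondrial limit, resolution 0.5 and clustering without called genes, with the lowest value at resolution 0.5 (0.89). Without wild type 1 the calls of Cdca3 (-1.51), Dock10 (-0.80), Ttc3 (0.94) and Blm (0.99) were lost. Also lost were those of Ttc3 (1.16) and Blm (1.16) without Y641F 1, that of Blm without wild type 2 (1.14) or Y641F 2 (1.17), and that of Cdca3 without Y641F 2 (-1.22).

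The fifth comparison summed all B cells of a mouse, so that the mix of classes enters it. Serpinb1a, a protease inhibitor, fell from 69.7 ± 8.60 to 22.9 ± 1.78 CPM (SD, n = 3; log2 -1.60, SE 0.127, adjusted p = 5.94e-03, edgeR), and Lmo2 from 65.3 ± 6.67 to 21.8 ± 6.46 CPM (log2 -1.57, adjusted p = 0.0210). Gng12 (-1.35), Pigp (-1.27), Ttc3 (-1.24) and Sgk3 (-1.22) fell as well. Lxn (0.91), an inhibitor of carboxypeptidases, Suclg2 (0.89), Prkca (0.70) and Slc25a39 (0.64) rose. In all 83 of 10551 genes passed, 17 higher and 66 lower. The memory and egress list passed as lower (median log2 -0.28, S1pr1, a receptor for egress from tissue, fell by 0.83 on the log2 scale, and 7 of 22 fell when adjusted over the list alone, camera adjusted p = 3.07e-05, adjusted p = 0.617 with an estimated correlation). Memory markers, which but for Vim and S100a10 are all in that list, passed as lower too (median -0.33, 6 of 17 when adjusted over the list alone, camera adjusted p = 2.62e-05, adjusted p = 0.617 with an estimated correlation). Light zone (median -0.12, camera adjusted p = 0.0150, adjusted p = 0.933 with an estimated correlation), G2/M (median -0.19, camera adjusted p = 1.32e-03, adjusted p = 0.938 with an estimated correlation), MYC-linked (median -0.16, camera adjusted p = 0.0167, adjusted p = 0.938 with an estimated correlation) and PRC2-target genes (median -0.05, camera adjusted p = 0.0269, adjusted p = 0.867 with an estimated correlation) also passed as lower. Without Y641F 2 the light zone, G2/M and MYC-linked lists did not pass (adjusted p = 0.0885, 0.743 and 0.133). The same held for the light zone list without wild type 1 (0.322) or Y641F 3 (0.149), the MYC-linked list without wild type 3 (0.245) or the PRC2-target list without wild type 2 (0.0631), wild type 3 (0.0976), Y641F 1 (0.287, with the median turned to 0.05) or Y641F 3 (0.164). Over the left-out libraries the medians ranged from -0.25 to -0.05 for light zone, -0.28 to -0.02 for G2/M (the latter without Y641F 2), -0.23 to -0.07 for MYC-linked and -0.36 to 0.05 for PRC2-target genes. With the mouse number as a block, 500 genes passed and the PRC2-target list did not (adjusted p = 0.0741). The count was 339 without Y641F 1, 39 without Y641F 2, 19 without Y641F 3, 16 without wild type 1, 4 without wild type 2, 1 without wild type 3 and 235 with DESeq2. Each of the 10 named genes lost its call without at least 1 library. Of them, 9 did not pass with a 5% mitochondrial limit, 6 with a stricter count filter and 5 with thinned cells.

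The sixth comparison took plasma-like cells, which carry markers of antibody-secreting cells. Whether they descend from GC B cells was not tested. Cd93, a surface protein of plasma cells, fell from 88.5 ± 9.39 to 14.3 ± 2.44 CPM (SD, n = 3; log2 -2.68, SE 0.162, adjusted p = 2.41e-07, edgeR). Cldn7, a tight junction protein, rose from 8.17 ± 1.18 to 65.3 ± 29.6 CPM (log2 3.08, SE 0.304, adjusted p = 4.55e-05). Cxcr3, a chemokine receptor, rose from 33.2 ± 2.30 to 123 ± 36.3 CPM (log2 1.91, adjusted p = 4.55e-05). Pglyrp1 (2.10), a peptidoglycan recognition protein, Tmed6 (2.00), Cryba4 (1.90) and the metallothionein Mt2 (1.60) rose, and Pkd2l2 (-1.49), Evi5 (-1.48), Gng12 (-1.46), Gpr171 (-1.44) and Ccdc88a (-1.39) fell. Of 8602 genes, 864 passed, 359 higher and 505 lower, 41.6% of them higher. Most wild type plasma-like cells lay in cluster 4, led by Tnfrsf17, Fkbp11 and Cd93, and the largest plasma-like cluster of each Y641F mouse was cluster 2, led by Cldn7, Epcam and Oosp1. Cluster 10, the plasma-like cluster with the highest G2/M score, held 27%, 27.4% and 28.3% of the plasma-like cells of wild type and 16.4%, 9.6% and 26.8% of those of Y641F mice. Of 41 G2/M genes 20 fell and 21 did not pass (median log2 -0.74; Ccnb1 -1.07, Plk1 -1.09), of 32 S phase genes 11 fell (median -0.49), and of 32 plasma cell differentiation and secretion genes 16 fell and 3 rose (median -0.40; Fkbp11 -1.11, Tnfrsf17 -0.91, Irf4 0.42). These lists were not tested as groups in plasma-like cells. Of markers of other cells in the same sums, Hbb-bt (log2 1.16) of erythroid and Ctss (0.59) of myeloid cells passed as higher, and so did the naive and follicular markers Bank1 (1.23), Fcmr (1.22) and Foxp1 (0.44). Cluster 14 had the highest median doublet score of the plasma-like clusters (0.17) and a naive and follicular score of 0.724. It held 2.73%, 1.05% and 2.76% of the plasma-like cells of wild type and 8.59%, 1.66% and 5.25% of those of Y641F mice. Whether these naive and follicular markers rise without it was not read. The erythroid marker Tfrc (-1.07), the T cell marker Cd28 (-1.20) and the marginal zone markers Cd1d1 (-1.25), Mzb1 (-0.61) and Marcks (-1.28) passed as lower, of which Cd28 and Mzb1 are also in the plasma cell list. Within cluster 4 alone 186 genes passed, Cd93 fell by 2.00 and Cldn7 rose by 1.39 on the log2 scale. There Cxcr3 (0.79, adjusted p = 0.109), Cryba4 (1.07, adjusted p = 0.124) and Mt2 (0.52, adjusted p = 0.656) did not pass. The count was 265 without wild type 2, 347 without wild type 3, 525 without wild type 1, 557 without Y641F 1, 417 without Y641F 2, 1302 without Y641F 3 and 512 with DESeq2. Scaling by library size alone gave 891, of which 62.9% were higher. The 25 pseudogenes had a median log2 of -0.78 in these cells, with 14 lower.

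The seventh comparison took memory-like cells. Pcp4, a calmodulin-binding protein, fell from 62.9 ± 7.26 to 20.2 ± 2.45 CPM (SD, n = 3; log2 -1.64, SE 0.20, adjusted p = 5.76e-06, edgeR), Cd36, a scavenger receptor, from 148 ± 37.9 to 67.0 ± 16.3 CPM (log2 -1.21, adjusted p = 7.95e-05), and Lmo2 from 155 ± 4.68 to 67.5 ± 18.7 CPM (log2 -1.17, adjusted p = 2.15e-05). Snhg9 (-1.53), a noncoding RNA, Gpr34 (-1.21) and Kpna2 (-1.14), a nuclear import receptor, fell as well. Pik3r4, a regulatory subunit of the class III phosphoinositide kinase, rose from 23.5 ± 4.57 to 52.2 ± 5.80 CPM (log2 1.07, adjusted p = 2.64e-03). Taok2 (1.29), the metallothionein Mt1 (1.14), Fcer1g (1.12), Isg20 (1.11) and Cxcr3 (1.02) also rose. Of 7171 genes, 151 passed, 54 higher and 97 lower. Without Y641F 2 the calls of Taok2 (1.27), Mt1 (1.00), Fcer1g (0.64), Isg20 (1.06), Cxcr3 (0.95), Gpr34 (-1.37) and Kpna2 (-0.99) were lost. Also lost were those of Mt1 (0.81) and Fcer1g (0.82) without wild type 1, those of Isg20 (1.02) and Cxcr3 (0.80) without wild type 2 and that of Gpr34 without Y641F 1 (-1.26). The count was 25 without Y641F 2, 67 without Y641F 1, 75 without wild type 2, 99 without wild type 3, 307 without Y641F 3 and 53 with DESeq2. With a 5% mitochondrial limit, 6 of the 9 named genes that had a value did not pass, Pcp4 (-1.67), Cd36 (-1.56), Snhg9 (-1.57) and Pik3r4 (0.71) among them. With thinned cells 8 of 12 did not, Pik3r4 (1.05) and Taok2 (1.39) among them. Without cluster 12, a memory-like cluster that expresses cell cycle genes, Kpna2 (-0.67) and Fcer1g (0.90) did not pass. Of 35 G2/M genes, 4 fell, Nusap1 (log2 -1.03), Birc5 (-0.73), Cks1b (-0.59) and Cdk1 (-0.84), with a median of -0.44. Without cluster 12, 0 of 22 passed (median -0.32), and the list was not tested as a group in memory-like cells. In the same sums the erythroid gene Hbb-bt (log2 0.83) and the myeloid genes Tyrobp (1.02) and Fcer1g passed as higher. The 25 pseudogenes had a median log2 of -0.48 in these cells, with 10 lower.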

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

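The tests of carried-over RNA and of both explanations through ribosomal protein genes were chosen only after the results were seen. So were the list tests with thinned cells and with clustering without called genes, the count of genes not measured in thinned cells, and the restrictions to cluster 4 and to memory-like cells without cluster 12.

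A test of the difference itself (edgeR interaction, mouse as a block) set apart 43 genes whose genotype effect differs between light zone-like and cycling GC-like cells. The differences of log2 fold changes, light zone-like minus cycling, were 1.39 for Ttc3, 1.18 for Blm, 0.964 for Pigp, 0.691 for Gars, 0.62 for Eif2a and 0.549 for Neil1, and -1.35 for Cdca3, -1.35 for Birc5, -1.01 for Dock10, -0.971 for Ffar1, -0.957 for Uvssa and -0.821 for Ms4a4c. Birc5 and Ms4a4c passed without each of the 6 libraries in turn, but Birc5 did not with a 5% mitochondrial limit (-0.81), centring per library (-0.64) or thinned cells (-1.20), nor Ms4a4c with DESeq2 (-0.84) or thinned cells (-0.87). Of the 12 genes named, 12 did not pass with thinned cells, 11 with a 5% mitochondrial limit, and 10 each with DESeq2 and with centring. Gene signals outside the B cell comparisons came from 271 erythroid, 221 myeloid and 25 T cells among the kept cells, which a sort for YFP would remove if it were complete.

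The G2/M list passed camera as lower in light zone-like cells of Y641F mice (median log2 -0.54), but not with an estimated correlation (adjusted p = 0.617). Its medians in plasma-like (-0.74, 20 of 41 genes lower), memory-like (-0.44, 4 of 35, but 0 of 22 without cluster 12) and cycling cells (-0.14, 4 of 42) were negative too. With each cell thinned to one number of UMIs, the 7 genes still measured had a median of -0.421 (-0.794 to -0.503 without each library in turn, each time over the genes then measured), which argues against different lowest UMI counts per cell for these 7, while for the other 14 this cannot be told apart, since they were not measured. Clustering without called genes left the median at -0.359 over 18 genes (-0.663 to -0.309), which argues against a border drawn by the called genes as the whole cause. With an estimated correlation the list passed in neither setting (adjusted p = 0.390 and 0.863). Cell cycle genes that were not called stayed available to that clustering. The list was not tested with centring per library, where the interaction values of Birc5 and Cdca3 shrank to -0.64 and -0.31. The class border as such is therefore not excluded. RNA or cells of all cell cycle phases carried into the light zone-like sums cannot be told apart from a change within these cells: the S phase list moved by 1.37 ± 1.78 points of its cycling level and the G2/M list by -2.63 ± 0.457 points, a difference of 4 points, but carry-over from G2/M cells alone was not excluded. An effect of the Ezh2 genotype on mitotic genes stays open as untested.

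Of 25 pseudogenes tested, 25, 25, 24 and 25 had a negative log2 in light zone-like, cycling, plasma-like and memory-like cells, and 4, 18, 14 and 10 passed as lower. They were not tested as a group. Less RNA of ribosomal protein genes overall would lower both, but the medians of ribosomal protein genes lay above those of pseudogenes by at least 0.602. A strain segment on one chromosome would gather the genes, but the fullest chromosome held 22.2% of the 18 called in cycling cells. Reads shared between ribosomal protein genes and their pseudogenes were predicted to lower the pseudogenes but not the ribosomal protein genes in any class. Medians of ribosomal protein genes were 0.253, 0.138 and 0.171 in light zone-like, cycling and memory-like cells but -0.144 in plasma-like cells, where the prediction was not met. The mean difference of medians was 0.651. With the reads not analysed here, shared reads cannot be told apart from a change of expression. An effect of genotype stays open as untested.

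The 12 named plasma-like genes had a median size of change of 1.75 on the log2 scale. Without Y641F 2, which holds most cluster 2 cells, it was 1.56 and 12 of 12 passed. The genes were picked for large changes with mice that do not overlap between genotypes. Leaving out a mouse could hardly undo that, so no conclusion is drawn from it. Within cluster 4 the median size was 1.24, with 12 of 12 in the same direction and 9 passing, although Cldn7 dropped to 1.39 and Cxcr3, Cryba4 and Mt2 no longer passed. Within cluster 4 the mix of clusters as drawn is held fixed, so it does not give the differences that remain there. Cluster 4 was itself drawn on the same cells, with Cd93 among its leading genes, and Cldn7 and Cxcr3 are among those of cluster 2. A different mix of cells within cluster 4 is therefore not excluded, and no conclusion on the mix is drawn from these picked genes. A genotype difference within plasma-like cells stays a hypothesis found and tested on the same data.

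Splitting the 6 mice in other ways gives 10 splits, too few for a share under 0.05. In 1 of them, the real one, as many genes passed in all B cells (83, highest other 0), light zone-like (189, highest other 1), cycling (822, highest other 0), plasma-like (864, highest other 0) and memory-like cells (151, highest other 33) and in the interaction (43, highest other 5). For gene list tests 8 of the 10 splits gave at least the real 24 (highest other 44), and for class abundance 10 of 10 gave at least the real 0 (highest other 2).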

How the results depend on the processing

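The tests with a term for mice numbered 1, cluster 4 alone, other definitions of the light zone-like share, and plasma-like or memory-like cells without 1 cluster were chosen only after the data were seen. Over 25 settings, 1818 of 2102 values of named genes kept their direction and side of the threshold, 279 no longer passed, 2 newly passed and 3 reversed. Over 12 settings, 201 of 288 gene list values kept theirs and 87 no longer passed. The smallest class sums limit the depth of light zone-like and memory-like cells, and 3 mice per genotype limit the shares. The causes of the changes below were not tested.

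DESeq2 called 235 genes in all B cells, 58 in light zone-like, 492 in cycling, 512 in plasma-like and 53 in memory-like cells and 5 in the interaction. No count filter gave 191 in all B, 1298 in plasma-like and 239 in memory-like cells, and a stricter one 8 in all B, 405 in cycling and 574 in plasma-like cells. A 5% mitochondrial limit gave 4, 75, 334 and 6 in all B, light zone-like, cycling and memory-like cells, 17 in the interaction and a light zone-like share difference of -1.43 points. A higher minimum of genes per cell gave 89 in memory-like cells and 25 in the interaction. Centring per library gave 33 in light zone-like and 520 in cycling cells and 6 in the interaction, with Ezh2 at 0.32 in light zone-like cells. Thinned cells gave 20, 41, 294, 558 and 47 in all B, light zone-like, cycling, plasma-like and memory-like cells and 4 in the interaction, with Ezh2 at 0.10 in light zone-like cells. Clustering without called genes gave 95 in memory-like cells. Cluster 4 alone gave 186 plasma-like genes, with Ezh2 at 0.15. Scaling by library size gave 891 plasma-like genes, 62.9% of them higher against 41.6%. Gene list tests passed 0 times with an estimated correlation (8 at an unadjusted p under 0.05) and 0 times with fry (15), against 24 with camera (35).

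Without a block, 83, 189 and 151 genes passed in all B, light zone-like and memory-like cells. With the mouse number as a block, these counts were 500, 443 and 376. Ezh2 passed in cycling cells (log2 -0.25, adjusted p = 0.0298), and the PRC2-target list did not in all B cells. Beyond these, the block changed no call among 87 values of named genes and 24 of lists that had passed. The number block was not run for the interaction, which has the mouse as its block. In the single classes pairing was not settled: correlations of mice numbered 1, 2 and 3 were 0.167, 0.0138 and 0.0805 in light zone-like, 0.152, -0.0656 and 0.0906 in cycling, 0.189, 0.00346 and 0.12 in plasma-like and 0.13, -0.00171 and 0.118 in memory-like cells. Mice numbered 1 lay over 0.1 in each class and those numbered 2 under it. A term for mice numbered 1 gave 629 in all B cells.

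The light zone-like share difference of 0.146 points was -0.311 with a 20% mitochondrial limit, -0.197 with doublets kept, -0.966 at resolution 1.5, -0.676 with clustering without called genes, -0.575 without GC-like cells that match no zone and -3.02 over all GC-like cells outside the cell cycle clusters. It was 0.0714 at resolution 0.5, 2.51 with a higher minimum of genes per cell, 6.38 with thinned cells and 14.4 with centring per library.

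Leaving out each mouse in turn gave 1 to 339 genes in all B, 88 to 401 in light zone-like, 358 to 874 in cycling, 265 to 1302 in plasma-like and 25 to 307 in memory-like cells, 8 to 40 in the interaction and 18 to 38 gene list tests (38 without Y641F 1). The share differences ranged from -3.29 to 4.81 points for light zone-like, -3.11 to 17.7 for plasma-like and -9.66 to -6.12 for memory-like cells, and class abundance gave 0 to 0 calls. The Ighg1 share and its alternatives were not run, since its genes are not in the files.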

Other observations

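The tests in this part were chosen only after the results were seen.

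Of 6268 genes tested in light zone-like, cycling, plasma-like and memory-like cells, 25 passed in each of these 4 classes and in the same direction, 21 lower and 4 higher in Y641F mice. Lower were among others Gadd45g, Gng12, Lmo2, Gsn, Cd200, Hmgn3, Cdkn2c and Phb, and higher were AC168977.1, Hbb-bt, Cbfa2t3 and C130026I21Rik. Independent classes would give 0.0269 genes that pass in all 4, whatever their direction, but the classes share mice. Within 20 Mb of Ezh2, 82 genes were tested, of which 4, 5, 13 and 2 passed in the classes in that order and 1, Gng12, in each of them, with its start 19366258 bases from that of Ezh2. These are 4.88%, 6.10%, 15.9% and 2.44% of the 82, against 2.60%, 8.49%, 9.89% and 1.92% of the other genes tested in all 4 classes. The share was not tested, and neither was a strain or targeting difference linked to the Ezh2 locus, so for Gng12 that stays open.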
